A study of Caenorhabditis elegans with 4 samples.

How the data were processed

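RNA from whole Caenorhabditis elegans worms of a fer-15;fem-1 strain was measured on 4 one-colour (Cy3) Agilent microarrays. Per the labels' protocols, about 50000 worms in 10 mL were kept for 12 h at 20 °C with indole at 0.1 mM, 0.5 mM or 1.0 mM, or with none as the control. Their food was an Escherichia coli tnaA mutant, which lacks the tryptophanase that makes indole. Each dose had 1 array and no replicate.

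Per the file headers, the arrays carried design 020186, were scanned at 5 micron and were read with Feature Extraction 11.5.1.1, whereas the submitters' processing notes name version 10.7. The deposited spot intensity is the processed signal, which Feature Extraction corrects for background within 1 array, and no scaling between arrays was recorded. The authors' own value table is also an intensity on a linear scale. After averaging repeated spots, it equalled the processed signal within 0.001 on the log2 scale for at least 99.91% of the probes of each array, with column medians of 247.2, 259.8, 276.4 and 337.0. It is therefore neither logged nor centred. Any further step behind it is not given in the sources used here. The other deposited columns used are spot flags (0 or 1), which mark spots well above background, saturated spots and outliers.

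The 4 arrays lay on 1 slide and were scanned together, so slide and scan could not differ between doses. The array positions 1 to 4 followed the dose, so position and dose cannot be told apart. The Agilent spike-in spots lay at background on these arrays and gave no outside check of the scaling.

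Signals were taken as log2 and each array's 75th percentile was subtracted. Spots marked as outliers were left out, as were control spots, and repeated spots of a probe were averaged. Of 43603 probes, 34315 were named by matching their sequence name or unversioned RefSeq accession to the gene table of assembly WBcel235, and 9288 had no match. The array files name an older build, so only names and the order of genes were taken from that table. A gene's value was the mean of its probes that were well above background on at least 1 array. This gave 17545 genes, of which 12530 had 1 probe and 5015 had more. 10102 had a gene symbol.

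Of the probes, 34514 (79.16%) were well above background on the control array, 34535 (79.2%) at 0.1 mM, 35944 (82.43%) at 0.5 mM and 34345 (78.77%) at 1.0 mM. No spot was saturated. The 75th percentile signal was 2552, 2600, 2685 and 3666. The 1.0 mM array was therefore scaled down by 0.522 log2 units relative to the control. After this scaling the median gene at 1.0 mM lay at -0.146 log2 units against the control. The number of arrays limits the precision. For genes with several probes the median SD between probes of the log2 difference was 0.079 at 0.1 mM, 0.082 at 0.5 mM and 0.082 at 1.0 mM. This spread is technical and holds no variation between worm cultures.

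Each dose was compared with the control by a fold rule, at least 2-fold (1 log2 unit), for genes well above background on at least 1 of the 2 arrays, with no p-value. The test of dose was the slope per mM over the 4 arrays, fitted with limma 3.58.1 (lmFit and eBayes with an intensity trend) in R 4.3.3, with Benjamini-Hochberg adjustment at 0.05. It has 2 residual degrees of freedom, and departures from a straight line count as error. A gene below background on an array has only a bound there, so its fold is given as "at least", against the lowest signal among probes well above background or the probe's own signal if higher.

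35 gene lists were fixed before the data were examined. For each list and dose the median was placed among 10000 random lists of the same size, matched on mean expression in 20 bins, as a description of these arrays. Over the dose series the lists were tested with limma's camera at a preset correlation of 0.01 and with an estimated correlation. With an estimated correlation camera has only the 2 residual degrees of freedom of the 4 arrays. There 0 of the 35 lists passed. The sperm and yolk lists, with estimated correlations of 0.05 and 0.969, both had an adjusted p = 0.742. This setting was not simulated, so its adjusted p does not decide on any single list. Camera compares a list with the other genes, so its direction is relative to them. The named genes follow a rule fixed at the same time. It takes the 12 genes with a symbol that were highest and the 12 that were lowest against the control at each dose, measured on both arrays with their probes moving one way. It adds the 10 rising and 10 falling genes with the smallest p, and up to 4 members per list with the largest difference at 1.0 mM. It also adds cyp-35A1 to cyp-35A5, gst-4 and the hsp-16 genes, and up to 5 genes measured on only 1 of the control and 1.0 mM arrays in each direction. No probe was matched to gst-4, which was not analysed here. nhr-25, sma-6, wrt-2 and the neighbouring genes ugt-13 and cyp-13A8 fall outside this rule and were named after their values were seen.

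The steps were tested on simulated data. With 200 genes given known slopes among 17545, the dose test recovered 6% at a slope of 1, 36% at 2, 76% at 4 and 84% at 8, with 6 false calls. Of 17345 unchanged genes simulated with the fit's error, 6.878% passed the 2-fold rule at 0.1 mM, 6.965% at 0.5 mM and 6.809% at 1.0 mM, an error that also contains curvature of the dose response. A simulated list with a slope of 2 gave a camera p of 2.95e-79 and an unchanged list 0.93.

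Alternatives were quantile normalization, median centring, other filters on dim probes, the brightest probe per gene, the authors' value table, other fold rules, dose ranks, a fit without the intensity trend and leaving out each array. Background correction by normexp (offset 50) was run on the spots' median signal, because the files used here hold no mean signal. Its fit on the 1.0 mM array was distorted by 6 spots of high local background, so it was repeated with any background above 2 times the array median replaced by that median. This repeat, and leaving out arrays from the list tests, were chosen after seeing the data.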

Results

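The data are 4 expression profiles of whole worms, 1 each at 0 (control), 0.1, 0.5 and 1.0 mM indole, a molecule that many bacteria release and that the series places between bacteria and the nematode that feeds on them. The comparisons ask which genes differ from the control at each dose and which follow the dose. There were no replicates, so no difference at a single dose has a biological error or a p-value.

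At 0.1 mM indole the genes furthest above the control included P450, UDP-glycosyltransferase and transporter genes beside a glucocerebrosidase homologue, lectins and a lipid carrier. gba-2, the glucocerebrosidase homologue, was 111-fold higher. The UDP-glycosyltransferase gene ugt-8 was 37.1-fold higher and ugt-34 21.5-fold higher. The cytochrome P450 genes cyp-13A5, cyp-13A4, cyp-35A3, cyp-13A7 and cyp-33B1 were 28.2-fold, 24.5-fold, 19.1-fold, 19-fold and 13.8-fold higher. pgp-1, a P-glycoprotein transporter, was 23.8-fold higher and lbp-8, a lysosomal fatty acid carrier, 18.6-fold higher. The C-type lectin domain genes clec-210 and clec-169 were 47-fold and 19.4-fold higher.

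The genes furthest below the control at 0.1 mM differed by less. srx-101, a chemoreceptor gene, was 5.2-fold lower in the mean of its probes, ham-1 3.85-fold and rpi-1 2.88-fold, but their probes differed from each other with an SD of 3.19, 2.73 and 2.18 log2 units. The SCP-like extracellular protein gene scl-19 was 3.63-fold lower, the acyltransferase gene oac-32 3.46-fold and sysm-1 3.15-fold. Other chemoreceptor genes in this group were srw-64 (3.27-fold lower), sri-57 (3.21-fold) and sru-16 (2.85-fold), beside basl-2 (2.99-fold), tab-1 (2.91-fold) and cld-1 (2.87-fold).

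In all, 340 genes were at least 2-fold higher and 219 at least 2-fold lower at 0.1 mM, which was 3.308% of the 16900 compared. This lies below the 6.878% of 17345 simulated unchanged genes that passed the same rule at this dose with the error of the dose fit. At least 4-fold differences were found for 125 and 52 genes. With only genes measured on all 4 arrays the counts were 194 and 64. With normexp they were 127 and 24, which raised the share of higher genes among these from 60.82% to 84.11%.

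Of 75 measured P450 genes, 21 were at least 2-fold higher and 0 lower, and the median of 0.17 log2 units lay at the 100th percentile of the random lists, as did the medians of 7 other lists at this dose, ribosomal protein (0.12) and collagen genes (0.14) among them. Of 66 UDP-glycosyltransferase genes, 17 were higher and 0 lower, with a median of 0.25. Of 45 glutathione S-transferase genes, 6 were higher and 0 lower, with a median of 0.15.

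At 0.5 mM gba-2, UDP-glycosyltransferase, P450 and lectin genes were furthest above the control. gba-2 was 310-fold higher, ugt-34 271-fold, ugt-8 75.1-fold, ugt-33 67.3-fold and ugt-9 56.2-fold. cyp-33B1 was 74.6-fold higher, cyp-13A5 59.6-fold, cyp-13A4 51.2-fold and cyp-35A3 45.5-fold. The lectin genes clec-9 and clec-210 were 124-fold and 98.3-fold higher, and pgp-1 42.6-fold higher.

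Below the control at 0.5 mM stood 4 genes of SCP-like extracellular proteins. scl-20 was 9.66-fold lower, scl-11 6.27-fold, scl-13 5.16-fold and scl-19 4.59-fold. sysm-1 was 8.37-fold lower and oac-32 7.82-fold lower. The apoptosis gene ced-13 was 4.76-fold lower, srh-148 4.64-fold, the acyl-CoA dehydrogenase gene acdh-2 4.58-fold (SD between probes 1.27 log2 units), the collagen gene col-108 4.54-fold, sru-16 4.32-fold and the glutathione S-transferase gene gst-34 4.23-fold.

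At 0.5 mM 611 genes were at least 2-fold higher and 278 lower, which was 5.153% of the 17251 compared and also below the 6.965% of 17345 simulated unchanged genes at this dose. Among the P450 genes 27 were higher and 2 lower, and among the UDP-glycosyltransferase genes 23 were higher and 2 lower, with medians of 0.50 and 0.48. With normexp the counts over all genes were 279 and 66, and the share of higher genes moved from 68.73% to 80.87%. With only genes measured on all 4 arrays they were 389 and 125.

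At 1.0 mM the differences were larger and spread over many more genes. ugt-34 was 3210-fold higher, gba-2 2420-fold, clec-9 1390-fold and ugt-33 1140-fold. The P450 genes cyp-35A3, cyp-35B2 and cyp-35A1 were 891-fold, 664-fold and 405-fold higher. stdh-2 and dhs-23, which code for steroid or short-chain dehydrogenases, were 409-fold and 371-fold higher. ugt-9 was 354-fold higher, fipr-24, a gene related to fungus-induced peptides, 338-fold, and ugt-8 319-fold. Several of the largest folds rest, at all 3 doses, on dim control signals. These were 15.5 for ugt-34, 20.1 for gba-2, 25 for clec-9 and 16.8 for cyp-35A3, where the median signal of the control array was 245.4. The sizes of such folds are therefore uncertain.

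Among the genes furthest below the control at 1.0 mM, scl-20 was 118-fold lower, scl-13 53.9-fold and sysm-1 54.6-fold. pud-3, pud-1.1 and pud-2.1, first described as proteins raised in daf-2 mutants, were 108-fold, 58.1-fold and 52.7-fold lower. folt-2, a folate transporter homologue, was 78.5-fold lower, the collagen gene col-101 54.9-fold, the astacin protease gene nas-3 53.7-fold and vit-1, a yolk protein gene, 51.1-fold. clec-230 was 43.2-fold lower, or higher by 0.11 log2 units with normexp, and dhs-26 36.6-fold lower. With high backgrounds replaced clec-230 stayed lower.

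Some genes were measured on only one of these arrays. Above background at 1.0 mM and not in the control were the chemoreceptor genes sri-39 (at least 233-fold higher) and str-112 (at least 55.3-fold). The others were the antibacterial factor gene abf-3 (at least 177-fold), clec-206 (at least 99.6-fold) and cyp-35B3 (at least 53.9-fold). Above background in the control and not at 1.0 mM were the lipase gene lips-6 (at least 39.7-fold lower), scl-11 (at least 36.5-fold), bah-1 (at least 20.5-fold), nspf-1 (at least 16.7-fold) and dao-4 (at least 12.9-fold). With normexp bah-1, nspf-1 and dao-4 lay above the control at 1.0 mM, at 0.11, 0.52 and 0.46 log2 units. With high backgrounds replaced they stayed below it.

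Altogether 2033 genes were at least 2-fold higher and 2878 at least 2-fold lower at 1.0 mM, which was 28.6% of the 17172 genes compared, against 6.809% of 17345 simulated unchanged genes at this dose. At least 16-fold differences were found for 173 and 88 genes. Of 920 genes with several probes that passed the 2-fold rule, 916 had their probes all on one side of the control. Normexp gave 5893 higher and 803 lower, a share of 88.01% higher against 41.4%, and with 6 high local backgrounds replaced it gave 1198 and 1934.

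**Figure D1:**
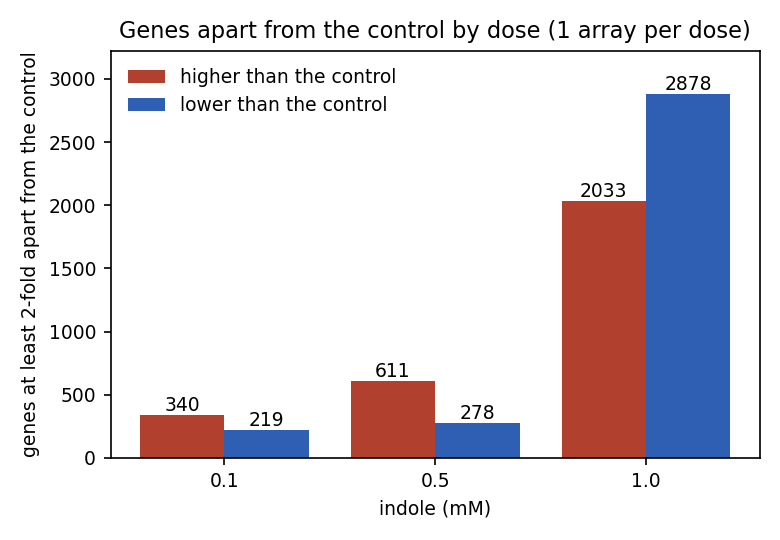
Number of genes at least 2-fold higher (red) or lower (blue) than the control at 0.1, 0.5 and 1.0 mM indole, 1 array per dose and no error bars. The bars reach 340 and 219 genes at 0.1 mM and 2033 and 2878 genes at 1.0 mM.

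P450 and UDP-glycosyltransferase genes were higher as groups at 1.0 mM. Of 75 P450 genes, 49 were at least 2-fold higher at 1.0 mM and 5 lower, with a median of 1.90 log2 units. The 5 cyp-35A genes were all higher, cyp-35A5 by 238-fold, cyp-35A4 by 131-fold and cyp-35A2 by 34.6-fold. In the dose test 10 of the P450 genes rose, 0 fell and 65 did not pass, among them cyp-35A3 (slope 8.31 ± 1.54 SE log2 units per mM, adjusted p = 0.0554). cyp-34A10 rose, by 7.60 ± 0.82 per mM (adjusted p = 0.0498). Adjusted over the list alone, 39 rose and 6 fell. By camera the list was shifted up with an adjusted p = 1.41e-08, and adjusted p = 0.742 with an estimated correlation. The cyp-35A and cyp-13A genes are close relatives, and a probe for one may bind the RNA of another. The median slope of the P450 list was 1.64 per mM, and 0.91 without the 1.0 mM array.

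Of 66 UDP-glycosyltransferase genes, 35 were higher at 1.0 mM and 9 lower, with a median of 1.25. By the dose test 8 rose, 2 fell and 56 did not pass. ugt-33 rose by 9.19 ± 1.1 per mM (adjusted p = 0.0498). Adjusted over the list alone, 32 rose and 8 fell. For this family camera gave an adjusted p = 2.16e-06, and adjusted p = 0.742 with an estimated correlation. Of 15 genes listed as targets of SKN-1, a regulator of detoxification, many of which also stand in another list, 5 were higher and 1 lower, led by ugt-16 (39.1-fold), dhs-8 (21.2-fold) and sdz-8 (18.1-fold). sdz-8 was the 1 list member that rose by the dose test, against 9 that rose and 1 that fell adjusted over the list alone. The SKN-1 list passed camera with an adjusted p = 0.00209, and adjusted p = 0.742 with an estimated correlation. For the UDP-glycosyltransferase list the median slope was 1.1 per mM, and 0.73 without the 1.0 mM array.

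Glutathione S-transferase genes went both ways. Of 45 measured, 15 were higher at 1.0 mM and 9 lower. gst-5 was 27-fold higher and gst-19 14.6-fold lower. 4 rose, among them gst-33 (3.71 ± 0.38 per mM, adjusted p = 0.0498), 2 fell and 39 did not pass, against 19 and 11 adjusted over the list alone. The list did not pass camera (adjusted p = 0.0613), and it passed without the 0.1 mM array (adjusted p = 0.0199) and without the 1.0 mM array (adjusted p = 0.00707). It also passed with normexp and high backgrounds replaced (adjusted p = 0.0409), where the median slope was -0.02 instead of 0.19.

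Of 51 ABC transporter genes, 12 were higher and 2 lower at 1.0 mM, with pgp-1 52.2-fold and pgp-14 49.2-fold higher and pmp-5 12.4-fold lower. 1 gene of this list rose, and 5 did adjusted over the list alone. Of 233 nuclear hormone receptor genes, 56 were higher and 34 lower. nhr-205, nhr-237 and nhr-178 rose, with differences at 1.0 mM of 27.7-fold, 22.9-fold and 23.7-fold, and nhr-259 was 25.0-fold lower, or higher by 0.30 log2 units with normexp. With high backgrounds replaced nhr-259 stayed lower. In this list 9 genes rose and 3 fell, against 49 and 13 adjusted over the list alone. Camera gave an adjusted p = 0.00209 for the ABC transporters and 0.000266 for the receptors, both with an adjusted p = 0.742 with an estimated correlation. Without the 1.0 mM array these were 0.274 and 0.12. The median slopes of 0.32 and 0.28 per mM were 0.85 and 1.11 with normexp, 0.21 and 0.04 with high backgrounds replaced, and the receptor slope was 0.08 without the 1.0 mM array.

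**Figure D2:**
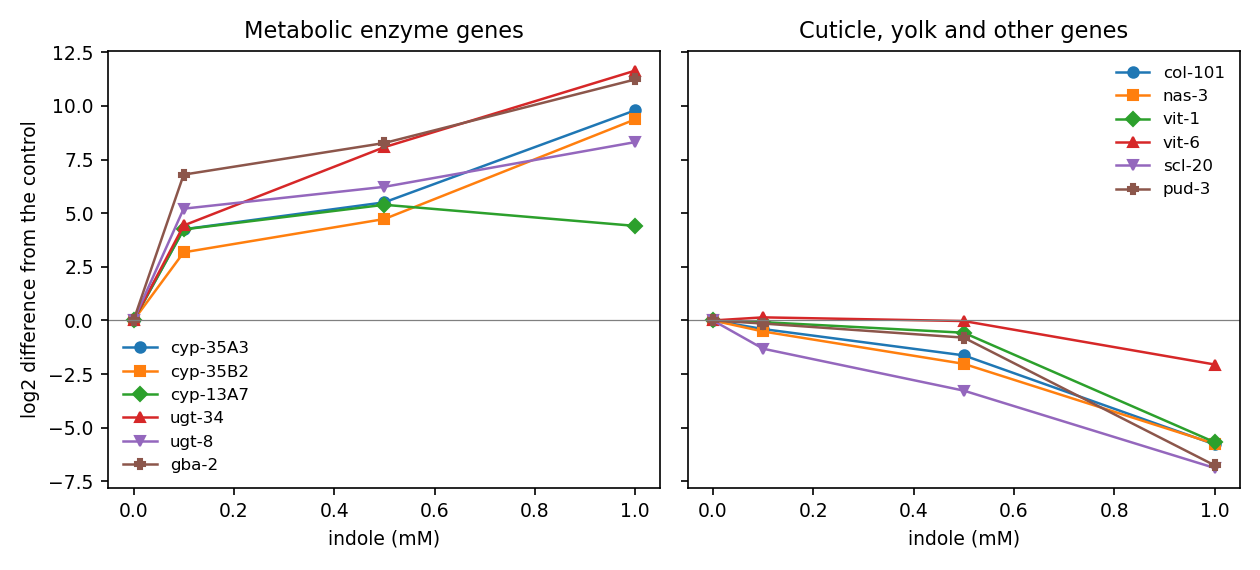
Log2 difference from the control against indole dose in mM for 6 enzyme genes (left) and 6 genes with lower values at 1.0 mM (right), 1 array per dose and no error bars. ugt-34 climbed to 11.65 at 1.0 mM, cyp-13A7 stood at 5.39 at 0.5 mM and 4.41 at 1.0 mM, and scl-20 reached -6.88.

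Collagen genes were lower at 1.0 mM and not at 0.1 mM. Of 170 measured, 123 were at least 2-fold lower at 1.0 mM and 4 higher, with a median of -1.87 log2 units. At 0.1 mM the median was 0.14, with 1 gene higher and 2 lower, and at 0.5 mM it was -0.14, with 4 higher and 14 lower. sqt-1, rol-6 and col-17 were 22.5-fold, 20.8-fold and 20.2-fold lower at 1.0 mM, and each lay above the control at 0.1 mM, at 0.69, 0.68 and 0.87 log2 units. By the dose test 25 fell, 0 rose and 145 did not pass, while 59.4% of the list fell and 3 genes rose adjusted over the list alone. col-105 fell by 3.98 ± 0.20 per mM (adjusted p = 0.0274) and col-95 by 3.51 ± 0.20 (adjusted p = 0.0274). The collagen list was shifted down by camera with an adjusted p = 9.84e-12, and adjusted p = 0.742 with an estimated correlation. The median collagen slope was -1.93 per mM, -1.05 with normexp, -1.59 with high backgrounds replaced and -0.40 without the 1.0 mM array.

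Of 16 hypodermis markers, 11 of which also stand in another list, 11 were lower at 1.0 mM and 0 higher, with a median of -2.24. bli-2 and dpy-7, both cuticle collagens, were 19.3-fold and 13-fold lower, and bli-1 lay at -3.42 log2 units, or 0.38 with normexp. With high backgrounds replaced bli-1 stayed below the control. 1 of the 16 fell, the hedgehog-related gene grd-3 (2.74 ± 0.15 per mM, adjusted p = 0.0274), and 8 did adjusted over the list alone. These markers were shifted down by camera with an adjusted p = 0.00718, and adjusted p = 0.742 with an estimated correlation. Their median slope was -2.38 per mM, -0.38 with normexp, -2.05 with high backgrounds replaced and -0.26 without the 1.0 mM array.

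Of 136 molting genes, 61 were lower and 14 higher. grd-4 and wrt-4 were 20.2-fold and 13.7-fold lower, while the patched-related gene ptr-22 rose by 4.57 ± 0.18 per mM (adjusted p = 0.0228). 3 rose and 6 fell, against 7 and 14 adjusted over the list alone. The list was shifted down by camera (adjusted p = 0.0302, and adjusted p = 0.742 with an estimated correlation). The shift was not found without the 1.0 mM array (adjusted p = 0.97), with the filter on all 4 arrays (0.0536) or with normexp (0.89), where the median slope was 0.60 instead of -0.85. With normexp and high backgrounds replaced it was found (adjusted p = 0.0389, median slope -0.64).

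Of 5 yolk protein genes, 2 were lower at 1.0 mM. vit-6 was 4.15-fold lower beside vit-1, while vit-4 and vit-2 were 1.68-fold and 1.5-fold lower. None passed the dose test over all genes, and 5 fell adjusted over the list alone. The yolk list passed camera with an adjusted p = 0.0189, and adjusted p = 0.742 with an estimated correlation. It was 0.0521 with normexp and high backgrounds replaced. The median yolk slope was -0.71 per mM, -0.46 after quantile normalization and -0.20 without the 1.0 mM array.

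Of 74 major sperm protein and related sperm genes, 9 were at least 2-fold higher at 1.0 mM and 0 lower, and the median was 0.04, 0.29 and 0.67 log2 units at the 3 doses, or 1.2 at 1.0 mM without scaling. 18 rose and 0 fell, against 49 and 0 adjusted over the list alone. gsp-3, a sperm phosphatase, and spe-46 were 2.22-fold and 2.10-fold higher. The sperm list had the smallest camera value, an adjusted p = 2.51e-20, and adjusted p = 0.742 with an estimated correlation. Oocyte and germline genes differed less, with a median of -0.21 at 1.0 mM, or 0.31 without scaling, and 0 of 29 at least 2-fold apart. cpg-1 and oma-2 were 1.29-fold and 1.26-fold lower. None passed the dose test, over all genes or adjusted over the list alone. Camera gave an adjusted p = 0.0037, and adjusted p = 0.742 with an estimated correlation. It was 0.584 after quantile normalization, 0.0765 with normexp and high backgrounds replaced and 0.061 without the 1.0 mM array.

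Of 139 insulin and neuropeptide genes, 37 were higher and 9 lower at 1.0 mM, with a median of 0.44. The insulin-like gene ins-11 rose and was 19.5-fold higher, nlp-48 was 12.1-fold higher and ins-31 was at least 7.5-fold lower, or higher by 1.16 log2 units with normexp. With high backgrounds replaced ins-31 stayed lower. 9 rose and 2 fell, against 47 and 6 adjusted over the list alone. Camera gave an adjusted p = 1.04e-07, and adjusted p = 0.742 with an estimated correlation. The median slope of this list was 0.35 per mM, 0.65 with normexp and 0.29 with high backgrounds replaced.

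Immune genes went both ways. Of 111 lysozyme and antimicrobial genes, 28 were higher and 40 lower at 1.0 mM. 15 rose, 4 fell and 92 did not pass, against 31 and 36 adjusted over the list alone. The saposin-like gene spp-12 rose by 7.16 ± 0.16 per mM (adjusted p = 0.00832), the smallest adjusted p of all genes. fipr-24 rose by 8.21 ± 0.30 (adjusted p = 0.0213) and the caenacin gene cnc-1 by 6.70 ± 0.37 (adjusted p = 0.0274). Of 200 C-type lectin genes, 41 were higher and 66 lower, and 11 rose and 1 fell, against 32 and 33 adjusted over the list alone. Neither list passed camera (both adjusted p = 0.474). Their medians were -0.40 and -0.25 (0.12 and 0.28 without scaling) while camera's direction was up, and the mean slope of the antimicrobial list was 0.13 against a median slope of -0.46. With normexp both median slopes were positive, 1.40 for the lectins, which then passed (adjusted p = 0.00453), and 0.63 for the antimicrobial genes. With high backgrounds replaced the slopes were -0.35 and -0.45, and neither list passed (adjusted p = 0.811 and 0.304). The lectins passed without the 1.0 mM array (adjusted p = 0.00921).

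Among the small heat shock genes, hsp-16.1, hsp-16.2, hsp-16.41 and hsp-16.48 lay at 0.29, -0.32, -0.23 and 0.08 log2 units at 1.0 mM, while hsp-16.20 and hsp-16.21 were 7.63-fold and 7.14-fold higher and did not pass the dose test. hsp-12.6 and hsp-12.3 rose, by 2.13 ± 0.19 and 1.2 ± 0.12 per mM (both adjusted p = 0.0498). Of 15 cytosolic heat shock genes 3 were higher, of 20 antioxidant genes 4, led by the thioredoxin gene trx-1 (3.67-fold), of 19 endoplasmic reticulum stress genes 0, with 2 lower, and of 9 mitochondrial stress genes 0. None of these 4 lists passed camera (adjusted p = 0.193, 0.193, 0.218 and 0.874). Adjusted over each list alone, 3 heat shock genes rose and 1 fell, and none passed in the other 3 lists. Without the control array the heat shock list passed camera (adjusted p = 0.0035), as did the antioxidant list (adjusted p = 0.0416), and the heat shock list passed with normexp and high backgrounds replaced (adjusted p = 0.0482).

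**Figure D3:**
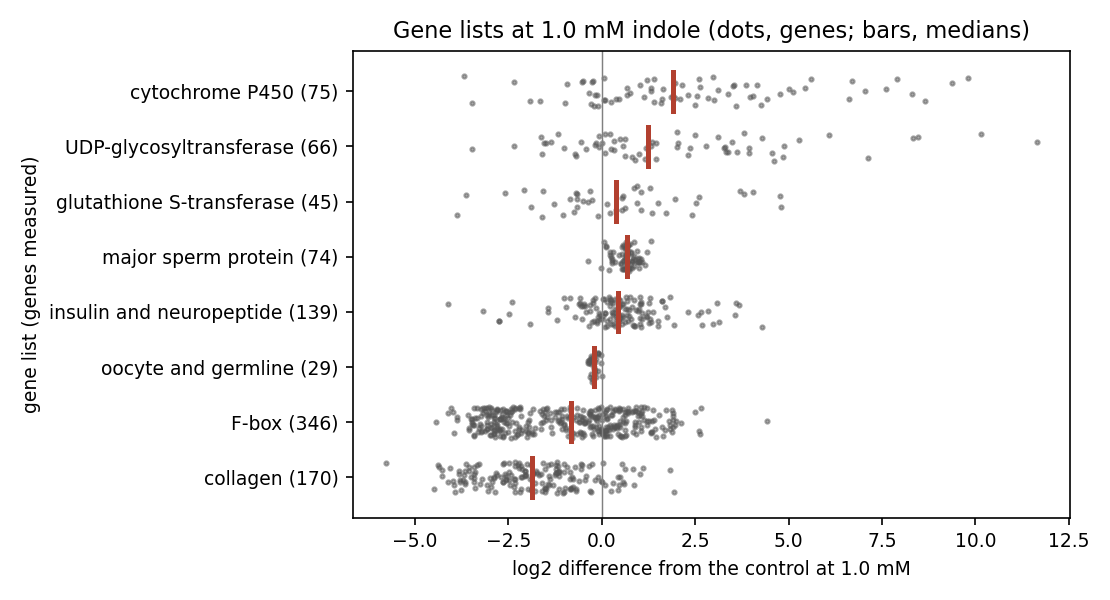
Log2 difference from the control at 1.0 mM for the genes of 8 lists, with 1 dot per gene, a red bar at each median and the number of genes in brackets. The medians run from 1.90 for the P450 genes to -1.87 for the collagen genes, and the 29 oocyte and germline genes lie close together around -0.21.

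Across the dose series, 329 genes rose and 159 fell by limma's slope at an adjusted p under the threshold, of 17545 tested. The rising genes with the smallest p included fipr-22 and fipr-23, related to fungus-induced peptides (3.88 ± 0.15 and 3.91 ± 0.18 per mM), the neuropeptide-like gene nlp-34 (2.82 ± 0.12), the phosphatase gene pho-6 (4.56 ± 0.21), srlf-34 (2.05 ± 0.10) and the flavin monooxygenase gene fmo-4 (2.69 ± 0.14). The falling ones included scl-20, scl-11, scl-12 and scl-13, with slopes of -6.55 ± 0.36, -5.29 ± 0.22, -4.20 ± 0.21 and -5.94 ± 0.36 per mM. The collagen genes col-135 and col-39 had slopes of -1.73 ± 0.12 and -3.38 ± 0.25, and gstk-1, a kappa-class glutathione transferase, of -1.33 ± 0.10. Many of the genes with the largest folds did not pass, because their values bent away from a line, as for gba-2 (adjusted p = 0.0858) and ugt-34 (adjusted p = 0.0545).

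The counts of this test rest on single arrays and on the threshold. Many named genes that passed, such as cyp-34A10, ugt-33, gst-33 and hsp-12.6, shared the same adjusted value just under it. With the authors' values 66 genes rose and 22 fell. The numbers of each list that rose or fell by the dose test over all genes carry the same limit. Without the control or without the 0.1 mM array no gene passed, without the 1.0 mM array 1 rose and 0 fell, and without the 0.5 mM array 3067 rose and 4118 fell. Each fit without 1 array has 1 residual degree of freedom, so lost calls need not come from the array left out. With dose ranks 9 rose and 1 fell, and at an unadjusted p under 0.05 the counts were 3209 and 4480.

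Values ordered from control to 1.0 mM without a reversal were found for 2189 genes upward (12.48%) and 3037 downward (17.31%), where a random order gives 4.17% each. In both directions together the real order, or its mirror, gave 5226 genes. With the control and 0.1 mM arrays exchanged, the same arrays still gave 3182. The differences of 0.5 mM against the control and of 1.0 mM against 0.1 mM share no array, and correlated across genes with r = 0.422. Simulated arrays without an effect gave 0.0017 on average and at most 0.0527. The other split without a shared array, 0.1 mM against the control and 1.0 mM against 0.5 mM, correlated less, with r = 0.144. There simulated arrays gave 0.0009 on average and at most 0.0478. Genes are not independent replicates. Between doses set against the same control, r was 0.658 for 0.1 and 0.5 mM (0.500 simulated), 0.409 for 0.1 and 1.0 mM (0.501) and 0.624 for 0.5 and 1.0 mM (0.501). The covariances were 0.188, 0.262 and 0.491, against 0.0996, 0.0998 and 0.1000 simulated. 472 genes were at least 2-fold higher at both 0.5 and 1.0 mM, where shared controls alone gave 126.8 and independent lists 75.01. For genes lower at both these doses the numbers were 253, 126.5 and 53.2. At 0.1 and 0.5 mM, 240 genes were higher at both (126.4 and 14.3). There 131 were lower at both, against 125.8 on average and at most 150 with simulated shared controls, and 4.58 for independent lists. At 0.1 and 1.0 mM the numbers were 225 higher (125.3 and 45.8) and 199 lower (127.0 and 44.5). The simulated lists were not matched in size to the real ones. Over all 17545 genes, the real lists held 259 and 310 lower genes at 0.1 and 0.5 mM. At 0.5 and 1.0 mM they held 642 and 2050 higher genes. The simulated overlaps therefore do not decide how much of the real overlaps comes from the shared control.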

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

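Probes that could not be matched to a gene were outside the comparisons of the report, and some of them stood apart from the control. At least 2-fold higher than the control were 160 of 5974 such probes at 0.1 mM, 283 of 6398 at 0.5 mM and 516 of 6113 at 1.0 mM, while 100, 107 and 865 were lower. Among the genes compared, 340 of 16900, 611 of 17251 and 2033 of 17172 were higher, and 219, 278 and 2878 lower. Of simulated unchanged genes, 6.878%, 6.965% and 6.809% passed the rule in either direction. No explanation was tested for these probes.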

How the results depend on the processing

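The repeat of normexp and the leave-one-out of gene lists were chosen after seeing the data. No paired analysis was possible because each dose had 1 array. Signal near background limits the counts. With the filter on all 4 arrays, genes higher at 0.1 mM and genes lower at 0.1 mM (340 and 219) numbered 194 and 64, and 375 were lower without a filter. For genes higher at 0.5 mM and genes lower at 0.5 mM (611 and 278) the same filter gave 389 and 125, and 497 lower genes without a filter. Against 2033 genes higher at 1.0 mM and 2878 genes lower at 1.0 mM, and the counts above, normexp gave 127 and 24 at 0.1 mM, 279 and 66 at 0.5 mM, and 5893 and 803 at 1.0 mM. With 6 high backgrounds replaced it gave 127 and 24, 279 and 66, and 1198 higher genes. A 1.5-fold rule gave 853 and 699, 1372 and 791, and 3600 higher genes at the 3 doses, and a 3-fold rule 166 and 75, 309 and 115, and 1133 and 1776. Quantile normalization, median centring, the brightest probe and the authors' values kept these counts within 1.5 times.

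The dose test (329 rising, 159 falling) gave 2043 and 1872 with normexp, 571 and 516 with median centring, and 292 falling genes with the all-array filter. It gave 460 falling genes with normexp and backgrounds replaced, 70 and 22 without a filter, and 66 and 22 with the authors' values. It gave 9 and 1 with dose ranks, 5 and 0 without an intensity trend, and 2985 and 3997 at an adjusted p under 0.1. Median centring moved the share rising from 67.42% to 52.53% and normexp to 52.18%, or 51.53% with backgrounds replaced. Of the 488 calls, 460 were shared with quantile normalization and 88 with the authors' values. Leaving out 1 array, with 1 residual degree of freedom, gave 0 to 3067 rising and 0 to 4118 falling genes. Many named genes that passed, such as cyp-34A10, ugt-33, gst-33 and hsp-12.6, shared the same adjusted value just under the threshold. A small change of input can therefore move such genes across it together. The authors' values equalled the processed signal within 0.001 log2 units for at least 99.91% of probes, yet kept 88 calls. Other causes of these differences were not tested.

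14 lists passed camera, 13 to 20 did under other processing, 11 to 17 without 1 array and 0 with an estimated correlation. The last setting has 2 residual degrees of freedom and decides on no single list. The glutathione S-transferase median slope of 0.19 was -0.02 with normexp and backgrounds replaced, where camera passed, and 0.14 to 0.39 without 1 array. Molting (-0.96 to -0.07) and histone (-0.48 to -0.03) lists turned in camera's direction without the 1.0 mM array, and the ribosomal protein list after quantile normalization (0.07). The correlation of 0.422 between separate arrays was 0.493 with the all-array filter.

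Under normexp as planned, these genes lower at 1.0 mM turned higher, with log2 differences of 1.48 for srx-101, 0.80 ham-1, 1.09 scl-19, 1.32 srw-64, 1.57 rpi-1, 1.37 cld-1, 1.47 sru-16, 1.41 ced-13, 1.5 srh-148, 1.62 acdh-2, 1.57 gst-34, 0.11 clec-230, 1.16 abu-6, 1.86 abu-7, 0.81 fbxb-108, 0.38 bli-1, 1.16 ins-31, 0.81 cat-2, 0.30 nhr-259, 1.75 pals-30, 1.67 pals-15, 1.02 rpl-24, 1.96 nkat-1, 0.11 bah-1, 0.52 nspf-1 and 0.46 dao-4. None of these 26 turned with the 6 backgrounds replaced. In that repeat the differences at 1.0 mM of 106 named genes moved by at least 0.252 log2 units, the root mean square SD between probes. Those of 86 moved less. rpi-1 was 0.16 by its brightest probe, and spe-42 -0.02 with backgrounds replaced.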

Other observations

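The tests of dose order, scaling, random lists, tissue share and stage were chosen after the results had been seen, and those of neighbouring genes before. The cadmium-responsive genes cdr-1 and cdr-4 were 77.0-fold and 24.0-fold higher and the metallothionein gene mtl-1 9.22-fold higher, while the osmotic stress gene gpdh-1 was 5.19-fold lower at 1.0 mM. Their list of metal and osmotic stress genes was not shifted by camera (adjusted p = 0.536). acdh-1, an acyl-CoA dehydrogenase that responds to vitamin B12, was 19.9-fold lower, and hphd-1 of the same propionate pathway 6.20-fold lower. Of 20 one-carbon and vitamin B12 genes, 4 were lower and 0 higher, and 12 fell and 2 rose adjusted over the list alone (camera adjusted p = 0.0503, from 6.3e-05 to 0.817 over its alternatives, of which 6 passed). Of 13 tryptophan and kynurenine genes 4 were lower. haao-1, an enzyme of tryptophan breakdown, fell by 2.72 ± 0.34 per mM (adjusted p = 0.0498), and bas-1 was 4.23-fold lower. Of 34 fatty acid genes 14 were lower and 4 higher, with the lipase gene lipl-1 8.80-fold lower. Adjusted over the list alone, 4 tryptophan genes fell, and 15 fatty acid genes fell and 6 rose. Neither list passed camera (adjusted p = 0.356 and 0.393), but with normexp the fatty acid list did (0.00616) and the tryptophan median slope was 0.26 instead of -0.36. With high backgrounds replaced the fatty acid list did not pass (0.869) and the tryptophan slope was -0.37.

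Of 346 F-box genes, 163 were lower and 44 higher at 1.0 mM, with a median of -0.83 (camera adjusted p = 0.0924, and 0.0101 after quantile normalization, 0.0117 without the 0.1 mM array and 0.00459 without the 0.5 mM array). The median slope of -0.72 was 0.64 with normexp and -0.59 with high backgrounds replaced, and no F-box gene passed adjusted over the list alone. fbxc-34 was 21.8-fold lower and fbxa-163 21.4-fold higher. Of 637 chemoreceptor genes 123 were higher and 27.63% lower (adjusted p = 0.932), and srr-4 rose and was 85.0-fold higher. The chemoreceptor median slope of -0.40 was 1.78 with normexp (adjusted p = 2.77e-07) and -0.47 with high backgrounds replaced (adjusted p = 6.31e-05), so the list passed in opposite directions of its slope. Ribosomal protein genes had a median of -0.14 (0.38 without scaling), with 1 of 77 lower, and his-24, a linker histone, was 8.71-fold lower among 56 histone genes (median -0.36, or 0.16 without scaling) of which 7 were lower and 1 higher, and none of either list passed adjusted over the list alone. Camera placed both of these lists down (adjusted p = 0.000263 and 0.0356, each with an adjusted p = 0.742 with an estimated correlation). Neither call held without the 1.0 mM array (0.908 and 0.817) or with normexp and high backgrounds replaced (0.0521 and 0.211), and after quantile normalization the median slope of the ribosomal list turned from -0.19 to 0.07 and the histone list lost its call (0.154). Intestine markers were higher for 3 and lower for 6 of 15, with the phosphatase pho-1 20.8-fold lower and the regulator elt-7 4.46-fold higher. Among 15 muscle markers 1 was higher and 0 lower, and among 18 neuron markers 0 were higher and 2 lower. Of 33 short-chain dehydrogenase genes 8 were higher and 7 lower. Of 31 pals and related genes 9 were higher and 6 lower. Of 19 metal and osmotic stress genes 6 were higher and 5 lower. Of 14 DAF-16 targets 2 were higher and 1 lower, and of 27 proteases of the cysteine and aspartyl classes 3 were higher and 8 lower. Of 8 genes of the aryl hydrocarbon receptor pathway 3 were higher and 1 lower. Adjusted over the list alone, 8 chemoreceptor genes rose and 0 fell, and 4 pals genes and 2 of the aryl hydrocarbon receptor list rose and 0 fell. By the same measure the numbers rising and falling were 2 and 1 for intestine, 1 and 7 for muscle, 2 and 1 for neuron, 6 and 5 for short-chain dehydrogenase, 4 and 5 for metal and osmotic stress, 4 and 2 for DAF-16 and 6 and 7 for protease genes. Other than the ribosomal protein and histone lists, no list of this paragraph passed camera with the processing of the report. Mean and median slope differed in sign for the aryl hydrocarbon receptor (0.26 and -0.09), pals (0.09 and -0.07), DAF-16 (0.20 and -0.02) and neuron lists (-0.14 and 0.03), and camera's direction was up for the intestine list despite its median slope of -0.25. Without the 1.0 mM array the intestine list had a median slope of 0.39 and passed (adjusted p = 0.0138), and the protease list had 0.15 instead of -0.48. With normexp the pals list had a median slope of 1.61 and passed (adjusted p = 0.00468), as did the muscle (0.0308) and protease lists (0.0312), and the aryl hydrocarbon receptor list had a slope of 0.87. With high backgrounds replaced the pals, muscle and protease lists did not pass (0.869, 0.71 and 0.958). There the pals and aryl hydrocarbon receptor slopes were -0.3 and -0.09. The DAF-16 slope was 0.06 with normexp or quantile normalization, and -0.04 with high backgrounds replaced.

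137 genes stood at least 2-fold above the control at 0.5 mM and at least 2-fold below that level at 1.0 mM. Of these, 73 were well above background on the 0.5 mM array alone, where the fold is no firm value, and 43 were so on both the control and 1.0 mM arrays, with medians of 0.86, 1.49 and -0.26 log2 units at the 3 doses. Among the 43, lbp-8 was 28.1-fold higher at 0.5 mM and 9.26-fold higher at 1.0 mM, and clec-169 was 39.7-fold and 5.06-fold higher. A pair of Agilent control probes of one kind was lower at 1.0 mM by more than the scaling, with log2 differences of -2.66 and -2.75. From the control to 1.0 mM their unscaled signals were 5621, 5149, 2823 and 1276, and 7198, 6833, 3652 and 1533. They thus fell in the order of dose and array position.

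Of the 24 orders in which the 4 doses can be given to the 4 arrays, 1, the real one, called as many as 488 genes, and the highest of the others called 0. This is the smallest share that 24 orders allow, and the test was chosen after the results were seen. It therefore does not exclude chance order of the arrays for the count. The count itself was 88 with the authors' values. It was 0 without the control or the 0.1 mM array, 7185 without the 0.5 mM array and 1 without the 1.0 mM array. Those fits have 1 residual degree of freedom, and array position followed dose.

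P450 and UDP-glycosyltransferase genes had higher medians at 1.0 mM, although 10 of 75 and 8 of 66 rose by the dose test and 2 of the latter fell. Neither camera call held with an estimated correlation (adjusted p = 0.742), but no list passed with that setting, so it decides nothing here. Scaling lowered the 1.0 mM array by 0.522 log2 units and could only reduce a rise, so the lowest of the 2 medians with and without it, 1.25, decides nothing. The P450 median lay at the 100th percentile of lists matched on expression, so it stood above genes of like brightness on this array. A few bright genes cannot move a median, so that explanation was not put to a test. The random lists were drawn gene by gene, whereas the P450 genes had an estimated correlation of 0.132. Other lists also reached the 100th percentile at 1.0 mM, the nuclear hormone receptors (median 0.35) among them. A response of these genes to indole stays open as a hypothesis, as do array position and differences between single cultures, since each dose had 1 array.

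Collagen and hypodermis genes were lower at 1.0 mM. Without scaling the collagen median was still -1.35, so the scaling does not account for its sign. An earlier stage at 1.0 mM may act as well and cannot be told apart. The oocyte and germline median was -0.21, above an assumed -1 (95% interval -0.28 to -0.17 from 10000 resamples of the 29 genes). The intervals in this paragraph hold the spread between genes and no variation between worm cultures. Yolk (-0.75, or -0.22 without scaling) and sperm genes (0.67, or 1.2) moved in the directions assumed for younger worms. The yolk genes moved unevenly, with vit-1 51.1-fold and vit-2 1.5-fold lower. Whether sperm genes mark the stage in this fer-15;fem-1 strain was not tested. A smaller share of hypodermis RNA also cannot be told apart from regulation of cuticle genes: 7 hypodermis markers had a median of -0.21 (-1.05 to 0.54), with nhr-25 at -1.87 and sma-6 at 0.54, and with the hedgehog-related genes grd-3 and wrt-2 (-2.72 and -2.96), left out of these, the 9 markers that are no collagens had -0.55 (-2.72 to 0.54). A shift in the phase of the molting cycle may also act on these genes and was not tested.

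Genes at least 4-fold higher at 1.0 mM lay next to each other on the chromosomes. Among 16565 measured protein-coding genes in the gene order of WBcel235, 729 were such genes and formed 133 adjacent pairs. In 10000 random sets of genes placed singly there were 32.1 on average and at most 59. These sets did not keep tandem copies together, so the excess speaks only against random placement of single genes. 46 of the pairs had symbols of 1 family, such as ugt-9 to ugt-13 and cyp-13A4 to cyp-13A8, where shared probes or shared origin may contribute. Another 28 had symbols of 2 families, against 9.1 on average and at most 22 in random draws. In these draws the 405 raised genes with a symbol were placed singly among the 9811 with one. The rest of the pairs had a gene without a symbol. Families were told apart by symbol prefix only, and the draws did not keep tandem groups together. The excess therefore cannot exclude tandem copies. Operons and shared regulatory regions stay open as untested, and among the same 16565 genes the 1175 at least 4-fold lower formed 273 adjacent pairs against 83.3 at random.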
